A study of Mus musculus with 6 samples.

How the data were processed

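Gene expression in epididymal white fat was measured on 6 two-colour spotted arrays, each hybridised with a pool of RNA of 6 mice given CL-316,243 and a pool of 6 mice given saline. The labels' description names the agonist CL316,246 in one place and the titles name it CL-316,243, which is used here. Per the labels' protocols, pooled RNA was made into cDNA labelled with fluorescein (Cy3) or biotin (Cy5), detected with a tyramide signal amplification kit, scanned, and quantified with QuantArray 3.0. The deposited values are log ratios of both channels, taken as log2, after a uniform scale factor between Cy5 and Cy3 and LOWESS in the authors' own program, per the labels. Which dye stood in which channel, which pool is the numerator, the log base, the background correction and the rule for dropping spots are not given in the sources used here. Base 10 was set aside because the highest value, 10.3, would exceed the range of a scanner; a natural log stays possible. Column medians lay between -0.015 and 0.006 and standard deviations between 0.42 and 0.79 (array 2). Each slide has a lot number of its own, so the lot could not be tested as a batch; batches of hybridisation, labelling and scanning are not given in the sources used here. No intensities were used here, so the signal behind a ratio is unknown.

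Arrays were grouped by the channel that holds the CL-316,243 pool, 3 arrays each. The labels describe 1 pool per treatment, so the 6 arrays count as 1 biological replicate; they entered the test as separate technical measurements, and the p-values cover array-to-array spread only.

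Columns were empty only at their ends (29, 724, 38, 169, 8 and 1 rows on arrays 1 to 6), and rows did not correspond between arrays. This had not been foreseen in the fixed design, and the placement was chosen after seeing the data. Each column was placed on probe numbers 1 to 19200 with a hidden Markov model in which a column can only lose spots. Normal scores of each array, clipped at 3, were predicted from the placed values of the other arrays in 3 rounds, and a lost spot was followed by another with probability 0.5. A value was kept where the posterior of its position was at least 0.95, which left 98.3%, 65.9%, 96.7%, 92.6%, 99.8% and 99.8% of probes on arrays 1 to 6. The placement uses agreement between arrays and so raises it. The placement was tested on data simulated with the losses it had itself inferred and a shared signal of the same size on every array. Of kept positions 91.4% to 98.0% were right on array 1, 92.2% to 98.6% on array 3 and at least 96.8% on the others (19200 probes, 3 simulations). The real gains in log-likelihood on arrays 2 and 3 (477 and 880) lay below the highest simulated ones (565 and 1244), and those of the other arrays above theirs. The share of right positions may therefore be lower on arrays 2 and 3. In 1 simulation of columns with nothing in common the same placement and test called 1 of 10681 probes, and 846 had an unadjusted p under 0.05. Those columns were normal noise, without the extreme values of the real ones. Array 2 was placed at 12.7% to 15.3% of probes in 2 such simulations, against 65.9% in the data. The count therefore does not give the rate of false calls in the real data. Placement with the sign of 1 orientation turned lowered the gain in log-likelihood on every array, from 2256 to 740, 477 to -201 and 880 to 646 on arrays 1, 2 and 3, and by little on the others (2205 to 2143, 3175 to 3075 and 1769 to 1657 on arrays 4, 5 and 6). In that placement 6 probes reached a mean of 1 in size in each orientation, 4 with the same deposited sign in both. Placement on absolute values, run after the agreement in sign had been seen, gave 72 such probes, 71 with the same sign, and mean correlations of signed values of 0.243 within and 0.082 across orientations. It placed as little as 24.0% of probes on 1 array, with a lowest gain of -15.6. Columns shuffled first gave 0 and 3 such probes when placed on absolute values and 0 and 1 when placed with their signs.

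Probe names came from the platform annotation, which lists 14717 of 19200 probes, 14711 with 1 symbol and 6 with several, which were not named; 4483 are unnamed here. Entrez identifiers matched current records for 14416, and 0 symbols changed. The match of names to numbers was checked on 1187 pairs of probes of one gene: their ratios, clipped at 2, correlated at 0.124, against -0.089 to 0.053 at 20 shifted numberings. By rank they correlated at 0.056 against -0.057 to 0.050, so by rank a wrong numbering reached the same size with the opposite sign. Of 168 partner probes of called probes 132 (78.6%) had the same sign, so a name read from 1 probe can be wrong. Gene values are the mean of a gene's probes; of 18 called genes with several probes, 15 had all probes on the same side.

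Log2 ratios were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with dye orientation coded as plus and minus 1. The deposited signs were used, and no array was sign-turned. The intercept is the dye-balanced ratio of the pools only if the same pool is the numerator on all arrays, which is not given. Probes and genes with at least 4 values, at least 2 in each orientation, were tested two-sided against 0 with Benjamini-Hochberg adjustment. Tested on simulated data with the real spreads and missing values over 18566 probes, the fit recovered 14% of changes of 0.5, 70% of changes of 1, 96% of changes of 2 and 100% of changes of 4 on the log2 scale (50 probes each), with 4 false calls among 144. The simulated noise was normal and independent between arrays, without misplaced rows or single arrays far apart from the others. These rates may therefore not hold in the real data. A size rule without a test counted probes of at least 1.5-fold with the same sign on every array. The tests, lists, naming rule and alternatives were fixed before the data were examined except where stated. For 18 gene lists and 13 cell type marker lists, members past the test were counted over all genes and adjusted over the list alone, and the list median was ranked among 10000 random lists matched on array-to-array SD in 10 classes, since no intensity was at hand. Lists added later are named where they are used. Placement, lists and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.

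Genes were named by a rule: the 15 largest positive and 15 largest negative ratios among called genes with the same sign and values on all 6 arrays, skipping clone names and predicted genes; the up to 4 largest ratios in each gene list; and Adrb3, Il6, Lep, Ppargc1a, Ucp1, Pdk4, Nr4a1, Fos, Adipoq and Socs3. List members named as passing, beyond these, and cell type markers were chosen after their values were seen.

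Alternatives were no dye term, median centring, scaling, stricter and looser filters, robust variances, array weights, a test against 1.2-fold, an adjusted p under 0.01, leaving out each array, each orientation alone, 1 probe per gene, and for lists unmatched random lists and camera with a preset correlation of 0.01 or an estimated one. The deposited row order and posteriors of at least 0.5 and 0.99 were added after seeing the data.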

Results

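Epididymal white fat of male C57BL/6J mice was compared between animals given CL-316,243, an agonist of the beta3-adrenergic receptor that triggers lipolysis in fat cells, and animals given saline. The mice were 12 weeks old, the dose was 1 mg per kg body weight, and tissue was taken 3 hr after injection. RNA of 6 mice per treatment was combined into 1 pool per treatment, and the 2 pools were hybridised against each other on 6 two-colour arrays. The CL-316,243 pool was in channel 2 on 3 arrays (arrays 4, 5 and 6) and in channel 1 on the other 3 (arrays 1, 2 and 3). The 6 arrays are repeat hybridisations of the same 2 pools, so every p-value below measures array-to-array spread and compares 2 pools, not the treatment across mice. The number of arrays limits the precision, and the spread between mice is unknown.

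The table held 19200 rows per array, and the columns were empty only in their last rows, from 1 row on array 6 to 724 on array 2. Row by row as deposited, rank correlations between arrays lay between -0.03 and 0.03. After each column was placed on probe numbers by allowing for dropped spots, arrays of the same dye orientation correlated at a mean Spearman rho of 0.28 over probes (range 0.09 to 0.42) and arrays of opposite orientation at 0.11 (range -0.01 to 0.18); probes are not independent replicates. Because the placement itself raises such values, columns simulated with nothing in common were placed the same way: their means reached 0.087 for the same and 0.099 for the opposite orientation, so the mean across orientations lay only slightly above that level. All values below rest on this placement. Single arrays stood apart for some genes: of 8004 genes with values on all arrays, 43 on array 3 and 11 on array 4 lay more than 2 log2 units above the median of the other arrays, and 83 on array 2 lay as far below it. On arrays 1, 5 and 6 at most 5 genes lay as far above it and 3 as far below.

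**Figure D1:**
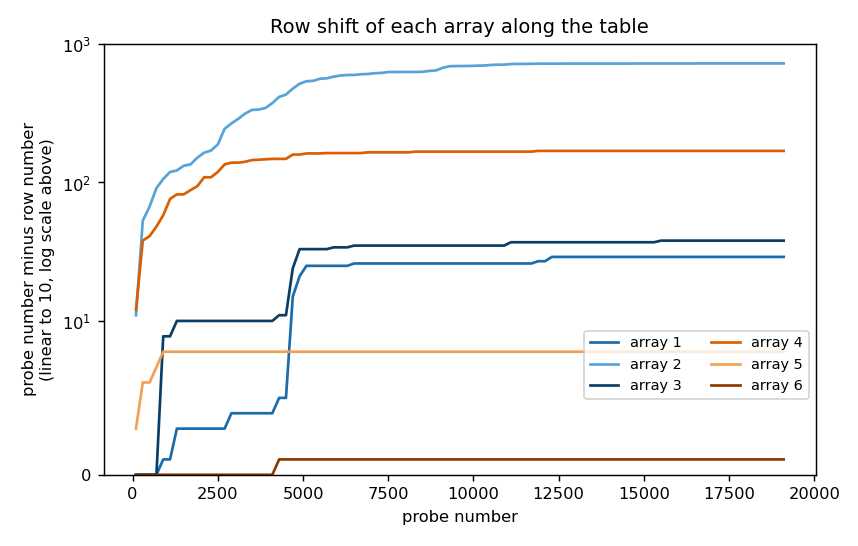
The horizontal axis is the probe number and the vertical axis the difference between probe number and row number, linear to 10 and logarithmic above, with a line per array. The shift reaches 724 rows on array 2, 169 on array 4, 38 on array 3, 29 on array 1, 8 on array 5 and 1 on array 6.

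Which pool is the numerator of the deposited log ratios is not given in the sources used here. Of the 91 probes with a mean log2 ratio of at least 1 in size in each orientation, 90 had the same sign in both. With the placement repeated on absolute values, in which signs play no part, 71 of 72 such probes had the same sign. Each array, in both orientations, is titled for tissue of the treated mice, although it holds both pools, so the titles do not settle the numerator. The CL-316,243 pool is a candidate numerator, weighed in the closing section. "Higher" and "lower" below mean higher and lower in the numerator pool, and every direction turns if the numerator is the saline pool. Where a gene's means in the orientations are given below without a label, the mean with the CL-316,243 pool in channel 1 comes first. Ratios are taken as log2; were the deposited values natural logs, each would be 1.44 times larger; the limma calls against 0 would not change, but every count by fold would.

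The 15 largest positive ratios included those of Hilpda, Noct, 2 chemokines and Il6. Hilpda, a lipid droplet protein induced by hypoxia and fatty acids, was 12.1-fold higher (log2 ratio 3.60 ± 0.17 SE, n = 6 arrays, limma adjusted p = 2.83e-05). Noct, a circadian gene also known as nocturnin, was 8.46-fold higher (3.08 ± 0.26). The chemokines Cxcl1 (2.50 ± 0.23) and Ccl7 (2.11 ± 0.19) and the cytokine Il6 (1.77 ± 0.19) were higher on all 6 arrays, as were the TNF family members Tnfrsf12a (2.41 ± 0.20) and Tnfsf14 (1.91 ± 0.17). Nfkbie, an inhibitor of NF-kappaB, reached 2.08 ± 0.18 and Dusp10, a phosphatase of stress-activated MAP kinases, 2.19 ± 0.24. The glucocorticoid receptor Nr3c1 was 4.00-fold higher (log2 ratio 2.00 ± 0.24).

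The other members of the 15 largest positive ratios were Serpina1f, Rtl8c, Fam110c, Coq10b and Uap1. Serpina1f, a serpin of the male reproductive tract, had the largest of these ratios at 4.68 ± 0.42 (25.7-fold). Uap1, which makes UDP-N-acetylglucosamine, was at 1.82 ± 0.15, Coq10b, a coenzyme Q binding protein, at 1.88 ± 0.21, Fam110c at 1.96 ± 0.19 and Rtl8c at 2.52 ± 0.19. Limma adjusted p-values of these 15 genes lay between 2.83e-05 for Hilpda and 0.00297 for Nr3c1.

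The genes that were lower included seminal vesicle transcripts and the transcription factor Klf15. Svs5, a secretory protein of the seminal vesicle, was 44.4-fold lower (log2 ratio -5.47 ± 0.48, limma adjusted p = 0.000653), Pate4, also a seminal vesicle protein, was at -2.73 ± 0.40 and Svs4 at -1.16 ± 0.24 (adjusted p = 0.0351). Klf15, a transcription factor of adipocyte and amino acid metabolism, was 2.62-fold lower (-1.39 ± 0.21, adjusted p = 0.00809). Txnip, an inhibitor of thioredoxin and of glucose uptake, was at -1.09 ± 0.11, Trp53inp1, a p53-inducible protein, at -1.33 ± 0.11 and the chemokine Ccl8 at -1.29 ± 0.13. The ratios of Txnip differed in size between the orientations, with means of -0.35 and -1.84. The dye term missed the threshold (limma adjusted p = 0.191). Chst1, a carbohydrate sulfotransferase, was at -1.28 ± 0.12, and Gbp8, an interferon-inducible GTPase, at -1.10 ± 0.10. Gjd4, Spryd3, Mat2b, Dock9, Mllt6 and Klhl24 completed the 15 largest negative ratios, between -1.10 for Gjd4 and -0.86 for Klhl24. The 3 probes of Klhl24 were all negative. Svs4 did not pass without array 1, 2, 4 or 5 (-1.20 to -0.97), Spryd3 without array 4 or 5 (-0.98 and -0.94) and Klhl24 without array 5 (-0.83).

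**Figure D2:**
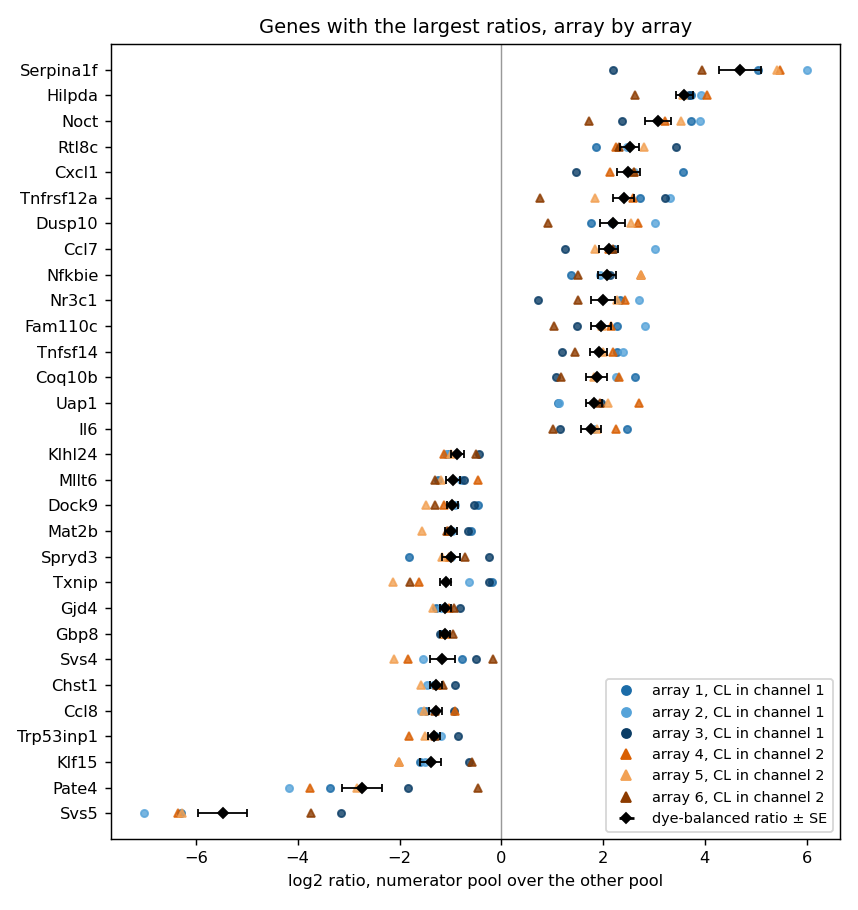
The horizontal axis is the log2 ratio of the numerator pool over the other pool, and each line is 1 of the 30 genes with the largest ratios past the test and values on all 6 arrays. Coloured points are the arrays, circles with the CL-316,243 pool in channel 1 and triangles with it in channel 2, and diamonds are dye-balanced ratios ± SE; every gene has the same sign on all 6 arrays, from Svs5 at -5.47 to Serpina1f at 4.68.

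Across 12890 genes tested, 401 passed the limma test at an adjusted p under 0.05, 246 higher and 155 lower, and 370 of them had the same sign on every array that measured them. A change of at least 2-fold was seen in 84 of the higher and 19 of the lower genes. At the level of probes, 718 of 18566 passed, 482 higher and 236 lower, of which 223 have no gene name here. By the size rule without a test, 652 probes differed by at least 1.5-fold with the same sign on every array, 452 higher and 200 lower. Fewer were tested when 1 array was left out. Without array 1, 4 or 5 the counts were 139 of 8299, 204 of 12854 and 127 of 11883 genes. In probes they were 170 of 12462, 370 of 18526 and 186 of 17342. The size rule gave 424 of 12462 probes without array 1 and 424 of 12518 without array 3, against 652 of 18566 with all arrays. The 3 arrays of each orientation alone gave 213 genes (CL-316,243 in channel 2) and 43 genes and 34 probes (channel 1). With the rows as deposited no gene passed, against 489 at an unadjusted p under 0.05, and no probe passed, against 699 unadjusted.

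**Figure D3:**
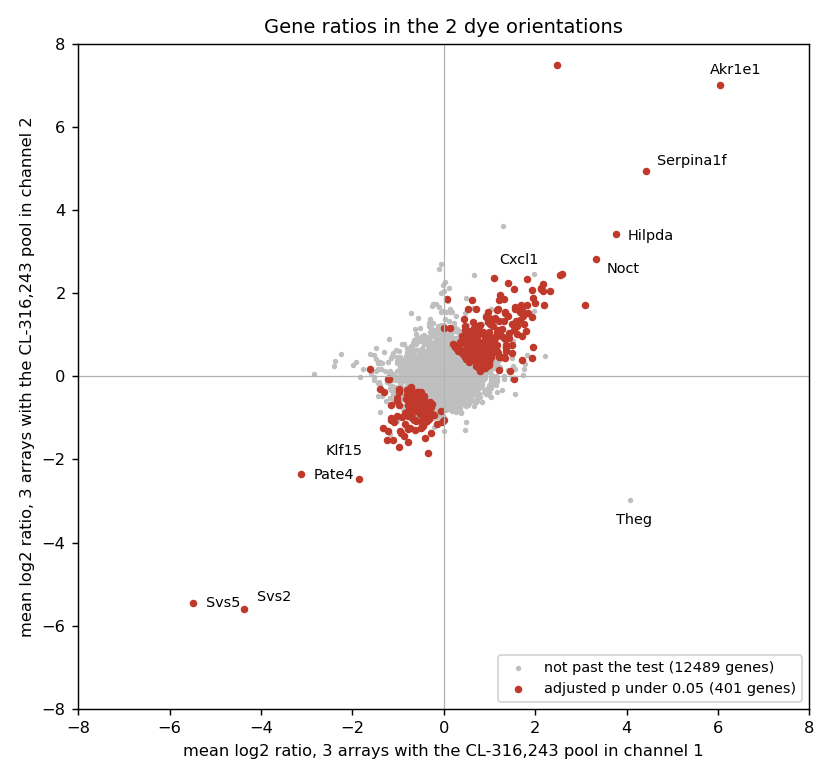
Each point is a gene, with its mean log2 ratio over the arrays with the CL-316,243 pool in channel 1 on the horizontal axis and in channel 2 on the vertical axis. The 401 genes past the test, in red, lie mainly in the lower left and upper right, with Akr1e1 at 6.05 and 7.01 and Svs5 at -5.49 and -5.46; Theg lies apart at 4.09 and -2.98.

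Of 24 tested genes of cAMP signalling and the immediate early response, 8 passed and all 8 were higher, and 14 passed when adjusted over the list alone, again all higher. Egr2 (1.70 ± 0.20) and Jund (1.33 ± 0.18), both immediate early transcription factors, Ier2 (1.31 ± 0.22) and Btg2 (1.14 ± 0.16), an antiproliferative gene, were among those that passed; Ier2 did not without array 1 or 4 (1.24 and 1.23). Fosl1 had the largest ratio, 2.46 ± 0.81 on 5 arrays, and did not pass (adjusted p = 0.153). Nr4a1, an orphan nuclear receptor and cAMP target, was at 0.31 ± 0.18 with 3 of 6 arrays positive and 0.10 without array 2, and Fos had too few placed values to be tested. The median of the list was 0.61, above all 10000 random lists (middle 95% from -0.12 to 0.12). It was 0.32 without array 1 and 0.39 without array 3, each on 13 members with enough values, and 0.38 without array 5, at percentile 99.92 or above in each fit without 1 array. Without array 4, where Fosl1 was at 7.64, its ratio was 1.45. Camera gave an adjusted p = 0.0659 with the preset correlation and an adjusted p = 0.62 with an estimated correlation, on the 11 members with values on all arrays.

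Among cytokines, chemokines and adhesion molecules, 4 of 24 genes passed, all higher: Cxcl1, Ccl2 (2.12 ± 0.33 on 5 arrays), Ccl7 and Il6. Adjusted over the list alone, 9 passed, all higher. The list's median of 0.18 lay at percentile 99.4 of random lists, but inside their middle 95% in 4 of the 6 fits without 1 array: it was 0.020 (percentile 71.3) without array 3 and 0.17 (90.2) without array 1, on 7 members each, 0.11 (93.8) without array 5 and 0.13 (95.1) without array 6. Without array 4 it was 0.29. Wrong numberings reached it too: with rows as deposited it was 0.22, and 3 of 200 shifted probe numberings gave a median as high, up to 0.25. Ccl2 did not pass without array 5 (2.01). The camera call (adjusted p = 0.0132) was lost with an estimated correlation (adjusted p = 0.37). Tnf was at -0.27 with all 6 arrays negative and did not pass (adjusted p = 0.222). In the acute phase and JAK-STAT feedback list, 2 of 16 passed, Cebpd (0.76 ± 0.15), a C/EBP transcription factor, and Stat3 (0.65 ± 0.10), the transcription factor downstream of Il6, and both were higher; 4 passed over the list alone, and the median of 0.07 lay at percentile 90.9, and at 74.0 (0.05) without array 1. Cebpd did not pass without array 4, 5 or 6 (0.71 to 0.79). Hp, haptoglobin, at 0.88 ± 0.38 (3.13 on array 3, at most 0.51 on the others) and Saa3, an acute phase serum amyloid, at -0.60 ± 0.30 (-2.57 on array 2 and -0.17 without it) did not pass, and Socs3 had too few placed values to be tested.

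In the list of heat shock and endoplasmic reticulum stress genes, 3 of 17 passed, all higher. These were Atf4, the transcription factor of the integrated stress response (1.69 ± 0.16, adjusted p = 0.000927), and the chaperones Hspa8 (0.82 ± 0.12) and Hspa1b (0.51). Adjusted over the list alone 8 passed, all higher, and 15 of the 17 ratios were positive; Ddit3 (0.72 ± 0.17) and Hspa5 (0.68 ± 0.19) passed over the list alone but not over all genes, except Ddit3 without array 3 (0.92) and Hspa5 without array 4 (0.86). Hspa8 did not pass without array 5 (0.78). The list's median of 0.25 lay above all 10000 random lists. Its camera call (adjusted p = 3.33e-05) was lost with an estimated correlation (adjusted p = 0.187). In the list of growth arrest, oxidative stress and metallothionein genes, 6 of 19 passed in both directions. Gadd45g (2.11 ± 0.18 on 4 arrays), the cell cycle inhibitor Cdkn1a (1.45 ± 0.27), Srxn1 (1.06 ± 0.18), Mt2 and Txnrd1 were higher and Txnip was lower. Without array 5 Cdkn1a (1.44) and Srxn1 (1.05) did not pass, nor did Srxn1 without array 1 (0.94). Over the list alone 10 passed, 7 higher and 3 lower, and the median of 0.0070 lay at percentile 56.8. That median moved when single arrays were left out: it was 0.46 (percentile 99.85) without array 1 and 0.53 (99.89) without array 3, on 6 members each. It was 0.20 (99.78) without array 4 on 18 members and 0.23 (99.27) without array 5 on 12. Without array 2 it was -0.012 on 19 members, and without array 6 it was 0.012 on 13. Where members dropped out, an effect of the array cannot be told apart from the change of members.

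Of 13 thermogenic genes of brown and beige fat, 2 passed and both were higher. These were Dio2, the deiodinase that activates thyroid hormone (1.18 ± 0.19, adjusted p = 0.0117), and Ppargc1a, a coactivator of mitochondrial biogenesis (0.77 ± 0.16, adjusted p = 0.0376). Dio2 did not pass without array 1 or 5 (1.1605 and 1.1999), nor Ppargc1a without array 1, 2, 4 or 5 (0.60 to 0.85). Ucp1, the uncoupling protein of brown fat, was at 0.49 ± 0.13 on 4 arrays and Kcnk3 at 0.45 ± 0.14, and both passed only over the list alone, where 4 passed, all higher. The list's median was 0.18, at percentile 99.6 of random lists, and 1 of 200 shifted numberings gave a median as high (0.27) and 4 one as large in either sign. Its camera call (adjusted p = 0.0202) was lost with an estimated correlation (adjusted p = 0.62). None of the 27 respiratory chain and citric acid cycle genes passed the limma test, over all genes or over the list alone; Cox5a (0.87 ± 0.34), Atp5o (0.80 ± 0.32), Cox7b (0.55 ± 0.15) and Sdha (-0.38 ± 0.14) had the largest ratios, and the median of -0.03 lay at percentile 32.6. Cox5a was at 3.52 and Atp5o at 3.12 on array 3, and without it they were at 0.37 and 0.32; Cox7b had means of 0.09 and 1.02 in the orientations. The median was positive without array 3, 5 or 6 (0.04, 0.05 and 0.01), -0.07 without array 1 and -0.02 without array 2.

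**Figure D4:**
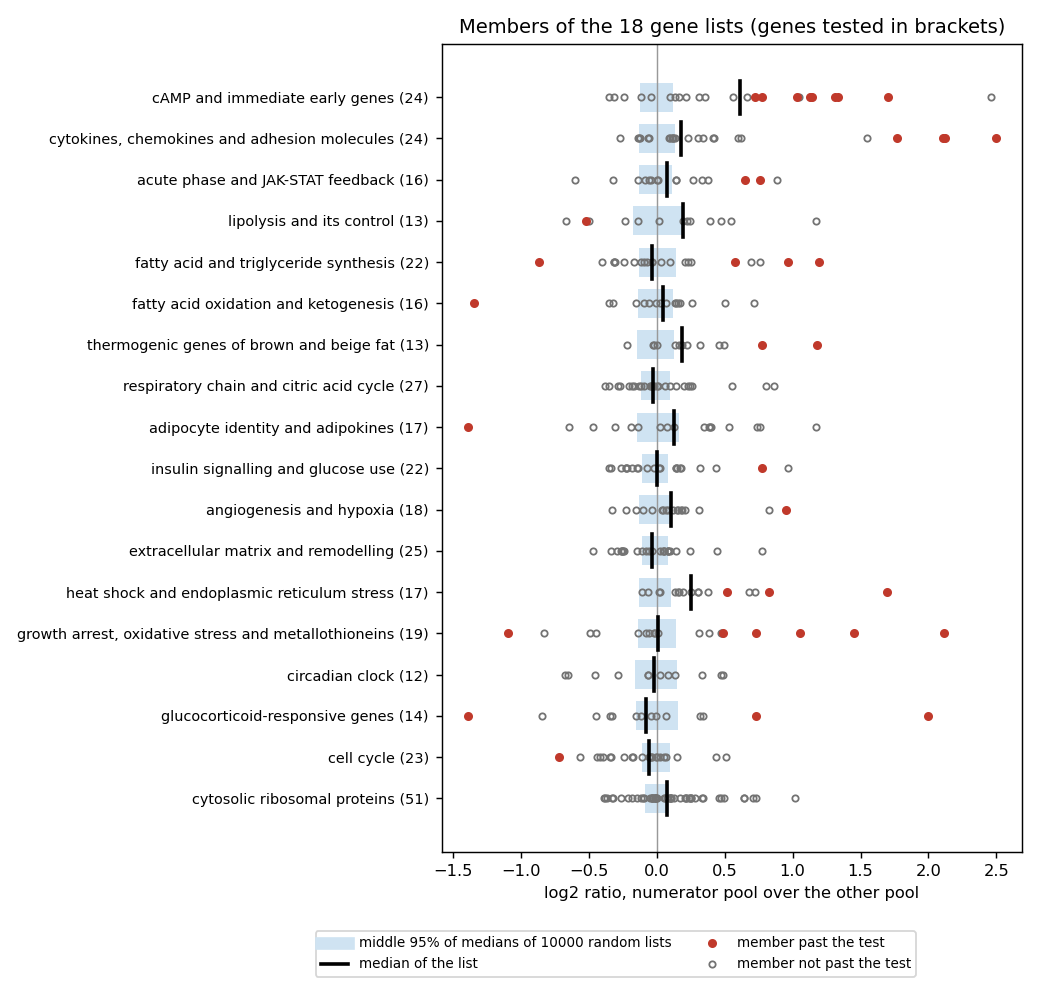
Each row is 1 of the 18 gene lists, with the number of genes tested in brackets, and the horizontal axis is the log2 ratio of the numerator pool over the other pool. Red points are members past the test, open points other members, black bars the list medians and blue bands the middle 95% of medians of 10000 random lists; 4 lists have medians outside their bands, from 0.18 for cytokines and for thermogenic genes to 0.61 for cAMP and immediate early genes.

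Genes of fat metabolism went both ways. In fatty acid and triglyceride synthesis, 4 of 22 passed. The triglyceride synthesis enzymes Dgat2 (1.19 ± 0.13), Dgat1 (0.58 ± 0.12) and Agpat2 (0.97 ± 0.12 on 5 arrays, 4 positive) were higher. Srebf1, the transcription factor of lipogenesis, was lower (-0.87 ± 0.12). Dgat2 had means of 1.93 with the agonist pool in channel 1 and 0.45 with it in channel 2. For Agpat2 these means were 0.06 and 1.87, so the larger one was in the opposite orientation. Over the list alone 6 passed, 5 higher and 1 lower, and the median of -0.04 lay at percentile 29.8. Without array 3 the median was 0.16, at percentile 97.6, and without array 1 it was 0.04 (76.1), each on 13 members. Without array 4 or 5 it was 0.05 (79.3) and -0.063. Lpl, lipoprotein lipase, at 0.76 ± 0.23 passed only over the list alone; it was at 2.29 on array 3 and at 0.46 without it. In fatty acid oxidation and ketogenesis, Ehhadh, a peroxisomal enzyme, alone of 16 genes passed and was lower (-1.34 ± 0.23 on 5 arrays), though not without array 4 or 5 (-1.36 and -1.25). Over the list alone 2 passed, and the median of 0.04 lay at percentile 80.9; it was 0.0078 (62.8) without array 6 and 0.09, 0.07 and 0.07 without array 1, 3 or 4. Ppara (0.72 ± 0.26, but 2.44 on array 4 and 0.41 without it), Slc25a20 (0.50 ± 0.13) and Eci1 (-0.36 ± 0.15) did not pass over all genes. Pdk4, pyruvate dehydrogenase kinase, was at 0.07 ± 0.10 and at 0.04 without array 2. Its means were 0.27 and -0.14 in the 2 orientations.

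In lipolysis and its control, Abhd5, the coactivator of adipose triglyceride lipase, alone of 13 genes passed and was lower (-0.52 ± 0.10, 6 of 6 arrays); it did not pass without array 1, 2, 4, 5 or 6 (-0.55 to -0.48). Cidec, a lipid droplet protein (1.17 ± 0.33, 3.17 on array 3 and at most 0.94 on the others), Fabp5 (-0.67 ± 0.24) and Prkaca, a catalytic subunit of protein kinase A (0.55 ± 0.18, with means of -0.06 and 1.16 in the orientations), did not; 7 passed over the list alone, 4 higher and 3 lower, and the median of 0.19 lay at percentile 97.1. It was 0.015 (percentile 60.0) without array 1 and -0.0032 (62.4) without array 3, on 4 members each, 0.031 (67.1) without array 4, 0.049 (71.2) without array 6, 0.13 (92.4) without array 5 and 0.064 (75.8) with 1 probe per gene; without array 2 it was 0.22 (98.4), outside the middle 95%. The beta3-adrenergic receptor gene Adrb3 has no named probe here. Of the adipocyte identity and adipokine genes, Klf15 alone of 17 passed over all genes and 9 over the list alone, 6 higher and 3 lower, with a median of 0.12 at percentile 94.1. Without array 1 or 3 the median was negative, at -0.19 (percentile 10) on 8 members and -0.14 (25.7) on 9. Leptin, Lep, was at -0.19 ± 0.10 (limma adjusted p = 0.347). All 3 arrays with the agonist pool in channel 1 were positive (mean 0.20). All 3 with it in channel 2 were negative (mean -0.58). Adiponectin, Adipoq, was at 0.34 ± 0.12 and Retn at 0.73 ± 0.36 (2.47 on array 3, at most 0.50 on the others), and neither passed over all genes.

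In insulin signalling and glucose use, Hk2, a hexokinase, alone of 22 genes passed and was higher (0.78 ± 0.17), also over the list alone, but did not pass over all genes without array 1, 4, 5 or 6 (0.67 to 0.85). The median of -0.0024 lay at percentile 56.2; it was 0.02 without array 2 or 3, 0.09 without array 4, and -0.0093, -0.034 and -0.067 without array 1, 5 or 6. Aldoa (0.97 ± 0.35, but 3.49 on array 3 and 0.47 without it), Pgk1 (0.43 ± 0.15) and Ppp1r3c (-0.35 ± 0.17, -0.21 without array 4) did not pass. In angiogenesis and hypoxia, Thbs1, thrombospondin 1, alone of 18 passed and was higher (0.95 ± 0.21; not past the test without array 5 or 6, at 1.10 and 1.02), also over the list alone, with a median of 0.10 at percentile 96.3. That median was -0.011 (percentile 51.3) without array 1 and -0.047 (46.5) without array 3, on 5 members each, and -0.014 (49.4) without array 6, but 0.12 (98.0) without array 2 and 0.14 (99.2) without array 4. Ccn1 (0.83 ± 0.23), Angptl4 (-0.33 ± 0.13) and Hmox1 (0.31 ± 0.14) did not pass. Of 25 extracellular matrix and remodelling genes 0 passed the limma test over all genes and 3 over the list alone, 2 higher and 1 lower, among them Col6a2 (0.77 ± 0.18); the median of -0.04 lay at percentile 29.3 and was 0.02, 0.03 and 0.01 without array 1, 3 or 6 and -0.0058 without array 5. Col15a1 was at -0.47 ± 0.13, Mmp9 at 0.44 ± 0.12 and Bgn at -0.34 ± 0.15.

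The circadian clock list had 0 of 12 genes past the limma test over all genes and 3 over the list alone, 1 higher and 2 lower, with a median of -0.02 at percentile 44.2 (0.04 without array 2, 0.03 without array 5, and -0.0032, -0.08 and -0.11 without array 1, 3 or 4). Its largest ratios were Bhlhe40 (-0.68 ± 0.17), Tef (-0.66 ± 0.15, past the test without array 2), Npas2 (0.48 ± 0.15) and Arntl (0.48 ± 0.18). Of 14 glucocorticoid-responsive genes 3 passed, Nr3c1 and Mt2 higher and Klf15 lower; 5 passed over the list alone, 2 higher and 3 lower, and the median of -0.08 lay at percentile 16.1; it was -0.012 (61.6) without array 3 and -0.13 (13.5) without array 1. Mt2 (0.73 ± 0.15) was positive on 4 of 6 arrays, with means of 1.53 and -0.07 in the orientations, and passed in 1 of the 6 fits without 1 array (0.88 without array 2; 0.62 to 0.78 in the others), and Hsd11b1 (-0.84 ± 0.21) did not pass over all genes, except without array 5 (-1.07). Of 23 cell cycle genes 1 passed, the replication helicase subunit Mcm6 (-0.72 ± 0.13; not without array 5 or 6, at -0.66 and -0.70), and 4 over the list alone, all lower, with a median of -0.06 at percentile 17.5. The median was -0.083 (4.81) without array 2, -0.18 (7.37) on 4 members without array 3 and -0.10 (5.35) without array 6. Mcm7 was at -0.56 ± 0.15 and passed without array 3 (-0.71), Cdk2 at 0.51 ± 0.20 (1.46 on array 4 and 0.31 without it) and Top2a at -0.44 ± 0.12. None of 51 cytosolic ribosomal protein genes passed the limma test, over all genes or over the list alone, and their median of 0.07 lay at percentile 95.5, and at 99.1 (0.12) without array 6. It was 0.02 without array 1 and 0.03 without array 3. Rpsa (1.02 ± 0.51), Rpl31 (0.73 ± 0.26), Rpl38 (0.71 ± 0.18) and Rpl7 (0.64 ± 0.28) had the largest ratios. Rpsa was at 4.53 on array 4 and at 0.40 without it, Rpl31 at 2.69 on array 3 and 0.36 without it, and Rpl7 at 2.68 on array 3 and 0.25 without it; Rpl38 had means of 1.49 and -0.06 in the orientations and passed without array 3 (0.92).

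Markers of other cell types were set beside these groups. Smooth muscle and pericyte markers had a median of 0.33, at percentile 99.99 of random lists, and 3 of 8 passed, all higher: Cnn1 (1.26), Des (0.90) and Acta2 (0.70); adjusted over the list alone 5 passed, 4 higher and 1 lower. Camera gave an adjusted p = 0.566 with the preset correlation and an adjusted p = 0.711 with an estimated correlation, on 5 members. The median was 0.14 (percentile 91.975) without array 1 and 0.016 (64.8) without array 3. Both rest on 5 of the 8 members, without Cnn1 and Des, so they do not show a loss of the signal over all 8. Adipocyte markers had a median of 0.28 at percentile 99.0, with 0 of 8 past the limma test over all genes and 3 over the list alone, 2 higher and 1 lower. Camera on 3 members gave an adjusted p = 0.603 and an adjusted p = 0.711 with an estimated correlation. The median was 0.19 (89.0) without array 1 and 0.15 (85.6) without array 3, each on 3 of the 8 members. Of 11 macrophage markers 1 passed, Mpeg1 (-0.69), and 3 over the list alone, all lower, with a median of -0.13 at percentile 7.54. That median was -0.027 (45.1) without array 6, -0.048 (24.6) without array 2, and -0.24 and -0.26 without array 1 or 3, on 6 members each. Of 8 endothelial markers 1 passed, Cldn5 (0.75), and 2 over the list alone, 1 higher and 1 lower, with a median of -0.12 at percentile 9.97 (-0.036 without array 4 and -0.18 without array 6). Krt18 (0.69) passed among 5 mesothelial markers (median -0.02, percentile 47.8) and Tnnc2 (1.19) among 8 skeletal muscle markers (median 0.05, percentile 77.9), in each case also alone over the list. By limma no marker passed over all genes among 10 of preadipocytes and fibroblasts (median -0.01, percentile 48.0), 9 of neutrophils (0.15, percentile 93.4), 7 of T cells (0.05, percentile 74.3), 6 of B and plasma cells (-0.09, percentile 20.7), 4 of mast cells (0.06, percentile 70.1), 3 of erythroid cells (0.02, percentile 59.2) and 8 of testis and epididymis (-0.04, percentile 35.1); over the list alone Prm2 (-0.65) of the last list passed and none of the others. Outside the middle 95% of random lists without 1 array were T cells without array 6 (-0.29, percentile 2.11) and B and plasma cells without array 3 (-0.36, percentile 1.67). Their highest medians without 1 array were 0.08 (array 3) and -0.00092 (array 2). The other medians ranged from -0.07 (array 4) to 0.05 (array 3) for preadipocytes and fibroblasts, 0.09 (array 5) to 0.20 (array 1) for neutrophils, -0.0065 (array 4) to 0.07 (array 2) for mast cells, -0.08 (array 3) to 0.20 (array 2) for erythroid cells, -0.01 (array 2) to 0.11 (array 3) for skeletal muscle, -0.02 (array 2) to 0.07 (array 5) for mesothelium and -0.07 (array 1) to -0.04 (array 4) for testis and epididymis. Mast cell, endothelial and mesothelial medians had too few members without array 1 or 3.

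By the limma dye term, 1 of 18566 probes followed the dye orientation, against 1937 at an unadjusted p under 0.05. That probe is named Theg, a gene of spermatids, and its mean ratio was -2.98 on the arrays with the CL-316,243 pool in channel 2 and 4.09 on the others (adjusted p = 4.10e-05). Without array 1 the dye term called 2 probes. Arrays correlated at a mean of 0.28 within and 0.11 across orientations, so the count of 1 does not mean that orientation had little effect. Were the ratios kept in channel order, this term would hold the difference between the pools instead.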

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

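The ratio of the probe named Theg followed the dye orientation. Its dye term was -3.53 on the log2 scale (limma adjusted p = 4.10e-05), with a mean of -2.98 over the 3 arrays with the CL-316,243 pool in channel 2 and 4.09 over the 3 arrays with it in channel 1, and its dye-balanced ratio of 0.55 did not pass the test (adjusted p = 0.124 over probes). The dye term called 1 probe in the real grouping of the arrays, and the highest count in another split of the 6 arrays into 3 and 3 was 1; in all, 3 of the 10 splits called as many. With 10 splits a share under 0.05 cannot be reached.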

How the results depend on the processing

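No paired analysis was possible because the arrays of both orientations share no numbers. The cause of a changed count was not tested unless stated. Counts of probes and genes past the test, 718 and 401, fell to 182 and 123 at an adjusted p under 0.01 and to 142 and 100 when tested against 1.2-fold, and rose to 1524 and 981 with array weights, which included all 401 genes. Leaving out 1 array gave 170 to 648 probes and 127 to 375 genes, with 12462 to 18526 probes and 8299 to 12854 genes tested. Channel 2 arrays alone gave 213 genes and channel 1 arrays alone 34 probes and 43 genes, from fewer arrays; 164 and 42 of these were among the 401. Median centring, scaling, both filters, robust variances, no dye term and both posteriors stayed within 1.5 times. The row order and posteriors were chosen after seeing the data. Rows as deposited gave 0 probes, 0 genes, 56 probes by the size rule and 0 for the dye term by limma (unadjusted 699, 489 and 720 for probes, genes and dye).

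The size rule fell from 652 to 165 probes at 2-fold and ranged from 424 to 740 without 1 array, where 12462 to 18526 probes were tested. The dye term called 1 or 2 probes without 1 array. Of 18 lists, 4 had medians outside the middle 95% of random lists, 7 with unmatched random lists, 2 with rows as deposited (cytokines at 0.22 and fatty acid oxidation at 0.19), and 0 by camera with an estimated correlation. Without 1 array the number was 4 to 6. The heat shock median was -0.070 with rows as deposited. The fatty acid and triglyceride synthesis median ranged from -0.063 to 0.16 without 1 array, the highest without array 3, on 13 of 22 members. Among the fits of 4 list medians past the test, 7 of 40 were no longer past it, 1 of them with the opposite sign; among those of 14 not past it, 13 of 140 passed, 1 of them with the opposite sign, and 28 changed sign without passing. Among 52 named genes past the test, 551 of 602 alternative fits stayed past it with the same sign, 51 did not pass, and 0 changed sign. Among 45 not past it, 15 of 470 fits passed and 1 changed sign. These fits covered no dye term, median centring, scaling, 1 probe per gene, both posteriors and leaving out each array, not the other alternatives. Fits in which a gene had too few values to be tested were not counted. Ccl2 and Cdkn1a, for example, were not tested without array 1 or 3. Gadd45g, on 4 arrays, was not tested without any of these. Genes on fewer than 6 arrays were thus tried in fewer fits. The genes with the largest ratios were chosen for 1 sign on all 6 arrays, so leaving out 1 array could not turn them. With rows as deposited, 259 of all 401 called genes kept their sign and 0 passed. No intensities were used here, so signal over background set no limit that could be checked.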

Other observations

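All tests in this part were chosen after the results they bear on had been seen, except the test of FoxO target genes and the counts over splits of the arrays. The 3 gene groups in the next 2 paragraphs were also chosen after their values had been seen, so their counts describe these pools and are not independent evidence.

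Of 9 tested genes of hexosamine and hyaluronan synthesis 4 passed the limma test, over all genes and over the list alone, all higher: Gfpt2 (1.59 ± 0.12 on 5 arrays), which feeds the hexosamine pathway, Uap1 (1.82 ± 0.15), Ugdh (1.62 ± 0.18), which makes UDP-glucuronate, and the hyaluronan synthase Has1 (1.82 ± 0.28 on 5 arrays). Gfpt1 (0.32), Ugp2 (0.10), Gnpnat1 (0.03), Has3 (-0.09) and Pgm3 (-0.24) did not pass. The list's median of 0.32 lay at percentile 99.8 of random lists. It was 0.13 (86.4) without array 1 on 5 members and 0.79 without array 3 on 6. Of genes outside the fixed lists, Plin2 was at 1.43 ± 0.26 on 5 arrays (limma adjusted p = 0.0256) and Plin4 at 1.01 ± 0.20 on 4 arrays (limma adjusted p = 0.0411), 2 genes also chosen after their values were seen.

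Of 16 cytosolic aminoacyl-tRNA synthetases 6 passed, 5 higher and 1 lower, and 8 over the list alone, 7 higher and 1 lower. Yars (0.73), Wars (0.61), Nars (0.57), Cars (0.55) and Eprs (0.53) were higher, Tars was at -1.07, and the median of 0.17 lay at percentile 99.8 (0.27 without array 6). Of 28 interferon-inducible genes 4 passed and all 4 were lower: Gbp8 (-1.10), Iigp1 (-0.84), Irgm2 (-0.78) and Psmb9 (-0.52). In all, 23 of 28 ratios were negative, with a median of -0.14 at percentile 0.41, and without 1 array of -0.36 (array 3) to -0.17 (array 2). Irf7 (0.49) and B2m (0.42), each positive on 5 of 5 arrays, and Psmb10 (0.17) did not pass over all genes; over the list alone 11 passed, 10 lower and 1 higher, which was Irf7.

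Arrays did not agree row by row as deposited. Columns that have nothing in common, such as failed or wrong hybridisations, were argued against, for the arrays as a set, by the mean rank correlation of 0.28 between arrays of the same orientation after placement, against means of at most 0.087 in columns simulated with nothing in common and a highest simulated pair of 0.199. The pair of arrays 2 and 3 was at 0.087, below that pair, though each array had at least 1 partner of its orientation at 0.233 or above. The mean of 0.111 across orientations was close to the highest simulated mean of 0.0991 and argues nothing. Rows renumbered after spots were dropped remain a candidate explanation, since the gain in log-likelihood from the placement exceeded the highest simulated gain (321) on 6 of 6 arrays, the lowest being 477.

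The largest ratios had the same sign in both orientations, which leaves the direction to be settled. A panel of genes fixed in advance as rising or falling after beta3-adrenergic stimulation was set against random panels. The median of 10 measured risers, 0.54, was reached in neither sign by 200 shifted probe numberings. It lay at percentile 99.5 or above (99.3 in another set of random draws) with all arrays, in each fit without 1 array and in each orientation alone. This argues against dye bias as the whole cause only if dye bias does not follow gene function. That was not tested, and the random panels were not matched on intensity. The difference between the risers and 3 measured fallers (-0.19) was 0.73, at percentile 99.75. It was 0.27 (86.8) without array 2 and 0.26 (78.8) with CL-316,243 in channel 1 alone. The fallers were Lep, whose sign differed between orientations, Retn at 0.73, and Srebf1 at -0.87. Of these only Srebf1, negative on 5 of 5 arrays, passed the test. By this difference, saline as the numerator (0.73) and CL-316,243 as the numerator (0.73), the candidate explanation, cannot be told apart. It depends on the few fallers. Without array 2 the risers stayed at 0.54, but Srebf1, with no value on array 3, was not tested. Lep and Retn were then left, at a median of 0.27. In channel 1 alone the fallers were at 0.20. With saline as the numerator the risers would be lower, so their median argues against saline for these 10 genes.

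Transcripts of male accessory glands differed between the pools. All 6 measured seminal vesicle genes were negative and 5 passed, Svs5 (-5.47), Svs2 (-4.98), Pate4 (-2.73), Svs6 (-2.17) and Svs4 (-1.16), while Ceacam10 (-1.28) did not. Seminal vesicle tissue dissected with the fat of the other pool may account for this, with a list median of -2.45, but the list was written after its members had been seen, and Spink1 (also named Spink3), of the testis and epididymis markers, was at -0.09. An epididymal source of the high Serpina1f (4.68, from 1 probe) was set against the 5 other epididymal transcripts tested. Their median was 0.015 (middle 95% of random lists -0.23 to 0.23), with Lcn8 (0.13), Lcn9 (0.01), Cst11 (-0.23), Cst12 (0.33) and Rnase10 (-0.11). This argues against that source only if these probes detect their transcripts, which cannot be checked without intensities. Regions of the tract that lack these transcripts were not covered. A response of the fat tissue to the agonist cannot be told apart from a difference between pools with 1 pool per treatment.

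Klf15, Txnip, Klhl24, Trp53inp1 (-1.33) and Cited2 (-1.01), all lower, prompted the hypothesis that targets of FoxO transcription factors were lower in general. The median of 16 FoxO target genes not chosen for their values was 0.022, inside the middle 95% of random lists (-0.13 to 0.10), and -0.048 to 0.059 without 1 array, at percentiles 31.6 to 87.1, and the 1 gene that passed, Btg1 (0.73), was higher, so this gave a negative result.

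The real grouping called 718 probes and 401 genes, and the highest counts among the other splits of the 6 arrays into 3 and 3, applied to ratios in channel order, were 1 probe and 0 genes. The placement had aligned all 6 arrays by their signed agreement. Every other split sets that shared signal partly against itself, so low counts there could be foreseen and are not evidence. In each case 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05.

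Large ratios outside the naming rule were Akr1e1, an aldo-keto reductase (6.53 ± 0.30 on 5 arrays), Crbn (4.99 ± 0.92 on 5 arrays, 4 positive, with 0.45 on array 2, -0.09 on array 3 and at least 6.56 on the others) and 2 unnamed probes, at 6.48 on 6 arrays and 4.11 on 5 arrays.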
